A study of Mus musculus with 24 samples.

How the data were processed

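Single haematopoietic stem cells (HSCs; lineage-negative, Sca-1 and Kit positive, CD150 positive, CD48 negative) from the bone marrow of a mouse strain with a cyan fluorescent protein (CFP) reporter were index sorted, so that the cytometer's values were recorded for the cell in each well. Per the labels' protocols, the cells went into 384-well plates with barcoded poly(T) primers, and their cDNA was pooled, amplified in vitro and sequenced. The authors deposited a table of unique molecular identifier (UMI) counts per gene and well, not normalized, with 27297 gene entries and 1536 wells, and an index-sort record of 1430 wells. Neither the UMI table nor the record names a sample, and the labels list 8 single-cell samples, so the table is a pool of these samples with no map from wells to samples. Per the submitters' processing notes, cutadapt, STAR, featureCounts, DESeq2, Bismark 0.19.0 and bcl2fastq 2.15.0.4 and the mouse builds mm9 and mm10 were used in the series, with no role given. The step from reads to UMI counts is not given in the sources used here. The bulk RNA-seq and bisulphite samples of the series were not analysed here.

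In the deposited record, CFP is the log10 of a whole channel number, per the values, and was used as ranks within a plate. The deposited channels for PE, PE-Cy5, PE-Cy7, APC, Alexa Fluor 700, APC-Alexa Fluor 750 and DAPI, and for scatter width and side scatter, were treated as a score and used as ranks within a plate, since no scale is stated. Forward scatter area is a linear intensity, per the file headers. The headers name dyes and no antibody, so the link from a dye to a surface marker is not known here. Spreadsheet errors stand in place of a value in 47 wells for PE, 14 for PE-Cy5, 77 for PE-Cy7 and 70 for DAPI, and these wells were left out for that channel. The deposited record also holds a whole number from 1 to 10 for each cell, with no meaning stated.

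The tests, gene lists, naming rule and most alternatives were fixed before the data were examined. They assumed 8 batches as replicates. The record instead names 4 sort plates (2, 3, 4 and 5), and these stood in for the batches as 4 technical replicates. The plates may hold cells of the same animals. The SEs and p-values of genes and of shares therefore rest on the spread between plates of a pooled collection of cells. Those of genes also rest on the spread over all genes. The p-values of the list test camera, described below, compare the genes of a list with the other genes and do not measure the spread between plates. None speaks to a difference between animals. With no map to animals, a stricter reading would take the whole table as 1 sample without a test, and the values per fraction stand under either reading.

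Cells with an index record and at least 500 UMIs were kept, which left out none of the 1430 recorded wells (511 UMIs or more). The 106 wells without a record held at most 502 UMIs and were not used. No doublet caller was run, because wells were filled by a single-cell sort. Within each plate the 20% of cells with the highest CFP were taken as bright, the 20% with the lowest as dim and the rest as intermediate, after the fractions that the labels give for the bulk samples. UMIs were summed per plate and fraction. These sums were tested in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood F test, plate as a block, Benjamini-Hochberg threshold 0.05), all 3 fractions in 1 fit. All fold changes are log2 with the edgeR SE. The residual degrees of freedom were 6 and the prior degrees of freedom 213, so the very small p-values borrow most of their precision from the spread over all genes. Total UMIs per library ran from 135701 to 172825 in bright, 267573 to 312170 in intermediate and 76354 to 84465 in dim cells, so dim libraries were the shallowest.

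For the cell-cycle rank, each of the 1025 cells with at least 1000 UMIs was thinned to 1000 UMIs. The 20% of a plate's cells with the most UMIs of the S phase and G2/M lists were compared with the 50% with the fewest, in the same edgeR test, with the list genes left out of the test and of the library sizes. In this fit the residual degrees of freedom were 3 and the prior degrees of freedom 103. The lowest value in the high set was 18 to 27 list UMIs across plates, and 56 of the 1025 cells lay within 1 UMI of it, so the sets are ranges of a score and not cell types. The S and G2/M share of a cell is the percent of its 1000 thinned UMIs from these lists. Shares and channel ranks were compared by an exact two-sided sign-flip permutation test over plates, whose smallest p with 4 plates is 0.125, so that these tests cannot reach 0.05. Gene lists were tested with camera (limma 3.58.1; inter-gene correlation 0.01, and again estimated) and fry, Benjamini-Hochberg adjusted over the lists with at least 3 tested members. Principal components were taken from 3702 genes detected in at least 5% of cells, without S, G2/M and ribosomal genes, centred within plate. The lists covered cell-cycle phases, growth, quiescence, stress, metabolism, retinoic acid and interferon response, ribosomal proteins, HSC and progenitor genes, and markers of megakaryocyte, erythroid, myeloid, lymphoid, mast, mature blood and endothelial cells. The mitochondrial genome list matched 1 gene entry and had 0 tested genes. The lymphoid progenitor, mast cell, mature neutrophil and endothelial lists had 1 tested gene each and were not tested as lists.

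Genes were named by rule: for each edgeR comparison the 15 highest and 15 lowest fold changes among genes past the threshold with a mean of at least 50 CPM and the same direction in every plate (planned as 7 of 8 batches, applied as 4 of 4 plates); the 2 to 4 members of each list with the smallest p; and 12 fixed genes where tested. From this set the text names a part, passing over genes with few UMIs in a fraction and further members of lists already shown, among them 6 genes whose call ended when a plate was left out, a choice made after seeing the data. A gene that the rule names is not reported here. Slamf1, Cd48 and Cdk6 had too few UMIs to be tested. Some entries join gene names (2109 of them), among these Kit, whose UMIs cannot be told from those of AK047175, and near-identical histone genes can share UMIs.

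On simulated counts with 200 changed genes, the bright and dim test (4438 genes) recovered 13.4% of 1.5-fold, 43.3% of 2-fold and 83.3% of 4-fold changes with 3 false calls among 4253 unchanged genes. The cell-cycle rank test (4215 genes) recovered 19.4%, 61.2% and 87.9% with 6 false calls among 4032. The simulated counts had the same spread for all genes and no differences between plates. Recovery and false calls in the real data can therefore differ from these values. Alternatives covered the test (DESeq2 1.42.0), normalization, count and cell filters, the width of the fractions, the plate block, cell size, cycling cells, thinning depth, list content and each plate left out. Further alternatives were chosen after seeing the data: 8 groups of wells made from odd and even plate columns in place of 4 plates, which are not independent replicates, fractions and sets chosen within 5 strata of UMIs per cell, CFP corrected for scatter width and side scatter, the 10 cells numbered 1 in the record, rich in haemoglobin UMIs, left out, and fits on the 50% of cells with the fewest S and G2/M UMIs or on random cells. Figures were drawn with matplotlib 3.10.9.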

Results

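HSCs of the reporter strain were studied as single cells, to ask how gene expression among HSCs relates to the brightness of the CFP reporter, which responds to retinoic acid signalling, and to cell-cycle status, the theme of the study's title. The 1430 index-sorted cells came from 4 sort plates with 356, 345, 361 and 368 cells. Plate totals were 483734, 545802, 516339 and 563679 UMIs. The median cell had 1265 UMIs and 821.5 detected genes, a shallow depth at which weakly expressed genes could not be tested. There were 286 CFP-bright, 858 intermediate and 286 dim cells. The plates are technical replicates of 1 pooled collection (n = 4). Errors and p-values of genes and shares rest on the spread between plates, those of genes also on the spread over all genes. The camera p-values compare genes within and outside a list, and no value describes the spread between mice.

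Genes of DNA replication and mitosis were far higher in CFP-bright than in CFP-dim HSCs. Of the S phase list, 31 of 39 tested genes rose and 0 fell, with a median log2 fold change of 1.60. Of the G2/M list, 37 of 46 rose and 0 fell, with a median of 1.80. Thymidine kinase Tk1 (3.18 ± 0.30, SE), the methylation cofactor Uhrf1 (3.07 ± 0.36), the kinetochore gene Spc24 (2.98 ± 0.31) and the mitotic kinase Aurkb (2.87 ± 0.57) had some of the highest fold changes. The linker histone genes Hist1h1a (2.98 ± 0.26) and Hist1h1b (2.96 ± 0.19) rose as much, and Hist1h1b went from 176 ± 62.0 CPM in dim to 1399 ± 583 CPM in bright cells (SD, n = 4 plates).

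Further replication genes that rose were the DNA ligase gene Lig1 (1.82 ± 0.20), the maintenance methyltransferase Dnmt1 (1.68 ± 0.18) and the replication clamp Pcna (1.68 ± 0.19). Topoisomerase Top2a (2.25 ± 0.21), the chromatin protein Hmgb2 (1.96 ± 0.18), the proliferation marker Mki67 (1.72 ± 0.42) and the tubulins Tuba1b (1.52 ± 0.08) and Tubb5 (1.29 ± 0.10) rose as well. Both lists passed camera, with adjusted p of 3.5e-46 for S phase and 1.1e-55 for G2/M, and each had an adjusted p of 0.0046 with an estimated correlation. The share of UMIs from the 2 lists after thinning was 2.37 ± 0.241% in bright, 1.12 ± 0.0975% in intermediate and 0.893 ± 0.0583% in dim cells (SD, n = 4 plates; 255, 611 and 159 cells). The bright minus dim difference was 1.47 ± 0.239 percentage points, and it was positive in 4 of 4 plates, from 1.18 to 1.76. The exact sign-flip permutation p was 0.125, the smallest that 4 plates allow. Bright cells also held more RNA molecules in the table: the median was 1871 ± 156 UMIs in bright and 1077 ± 85.4 in dim cells, a ratio of 1.75 ± 0.27, and the mean rank correlation of CFP with UMIs within plates was 0.400.

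**Figure D1:**
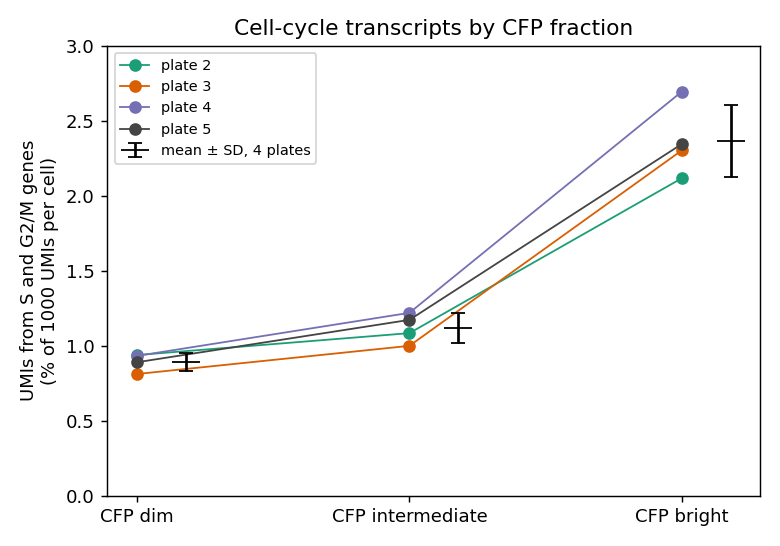
Percent of 1000 thinned UMIs per cell that came from the S phase and G2/M lists, as the mean over cells of each plate and CFP fraction. Points joined by lines are the 4 plates, and black marks are the mean and SD over plates; in every plate the bright cells lie highest, with a mean of 2.37% against 0.893% in dim cells.

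Growth genes rose with the same fraction. Of the G1 cyclin and growth list, 5 of 10 tested genes rose and 1 fell (median 0.76), among them Odc1 of polyamine synthesis (1.41 ± 0.32), the nuclear transport genes Ran (0.82 ± 0.14) and Ranbp1 (0.70 ± 0.15) and the G1 kinase Cdk4 (0.56 ± 0.12). Of the heat shock list, 5 of 10 rose (median 0.22), with the chaperones Hsp90aa1 (0.84 ± 0.18) and Hspa8 (0.37 ± 0.09). Oxidative phosphorylation showed 9 genes up and 2 down of 76 (median 0.17), with Uqcrc1 at 1.06 ± 0.24 and Cox7a2l at -0.65 ± 0.13. These lists passed camera upwards, with adjusted p of 0.00015, 0.0038 and 0.0038. With an estimated correlation, the adjusted p was 0.027 for growth, 0.117 for heat shock and 0.027 for oxidative phosphorylation. With fractions matched on UMIs per cell, a setting chosen after seeing the data, growth (median 0.36, camera adjusted p = 0.0653) and heat shock (0.036, 0.179) did not pass. With the 20% of cells highest in S and G2/M UMIs left out, oxidative phosphorylation (0.088, 0.0715) did not pass.

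HSC genes were lower in bright cells. Of the HSC list, 5 of 21 tested genes fell, 0 rose and 16 did not pass (median log2 fold change -0.68, camera adjusted p = 2.1e-06, and adjusted p = 0.027 with an estimated correlation). Ifitm1, an interferon-inducible membrane gene, fell by 0.99 ± 0.09, the transcription factor gene Hlf by 1.03 ± 0.18, Pdzk1ip1 by 0.79 ± 0.14, Mllt3 by 0.85 ± 0.24 and Mecom, a regulator of HSC self-renewal, by 1.10 ± 0.31. Without plate 5 the calls of Mllt3 (edgeR adjusted p = 0.0859, log2 fold change -0.76) and Mecom (0.0804, -1.04) ended, as did that of Mecom without plate 3 (0.0556, -1.08). The sorting-gate genes Kit (-0.40 ± 0.18) and Ly6a, which encodes Sca-1 (-1.28 ± 0.55), and Procr (-0.68 ± 0.35) did not pass, except that Ly6a passed without plate 2 (edgeR adjusted p = 0.0161, log2 fold change -2.23).

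Among quiescence genes, 2 of 6 fell (median -0.58, camera adjusted p = 0.0144; adjusted p = 0.0968 with an estimated correlation; 0.110 by camera without plate 2). These were Txnip, an inhibitor of glucose uptake (-0.92 ± 0.12), and the antiproliferative gene Btg1 (-1.35 ± 0.46), whose edgeR adjusted p was 0.0795 without plate 3 and 0.322 without plate 5, with log2 fold changes of -1.38 and -1.06. The CDK inhibitor Cdkn1c was at 0.41 ± 0.54 and did not pass. Of 62 ribosomal protein genes, 21 fell and 0 rose (median -0.18, camera adjusted p = 8.7e-07; adjusted p = 0.114 with an estimated correlation), with Rps9 at -0.41 ± 0.04 and Rps14 at -0.38 ± 0.04. The ribosomal list did not pass with fractions matched on UMIs per cell (median 0.0123, camera adjusted p = 0.769), nor with the cells highest in S and G2/M UMIs left out (-0.0133, 0.916), a setting in which the HSC list did not pass either (-0.15, 0.117).

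Cd74 and H2-Aa, genes of the MHC class II pathway, and Dusp2, a phosphatase gene, fell in bright cells. The mature B, T and NK cell list had 2 of 4 genes down (median -0.48, camera adjusted p = 0.0287; adjusted p = 0.122 with an estimated correlation; 0.0690 by camera without plate 2 and 0.0547 without plate 4), namely Cd74 (-1.26 ± 0.22) and H2-Aa (-0.65 ± 0.22). Matched on UMIs per cell, neither this list (camera adjusted p = 0.130) nor the immediate early list (0.0754) passed, nor with cells of at least 1000 UMIs (0.121 and 0.0741) or with the cells highest in S and G2/M UMIs left out (0.487 and 0.694). The immediate early list did not pass with CFP corrected for forward scatter (0.0665) either. Among all alternatives run, the mature B, T and NK cell list kept its call in 7 of 14 and the immediate early list in 5 of 14. The H2-Aa call did not hold without plate 3, 4 or 5 (edgeR adjusted p 0.0532, 0.437 and 0.125, log2 fold changes -0.76, -0.41 and -0.68). The immediate early list had 1 of 5 genes down, Dusp2 (-0.88 ± 0.26), with a camera adjusted p of 0.0287, an adjusted p of 0.114 with an estimated correlation, and camera adjusted p of 0.0875 without plate 2 and 0.0652 without plate 5. The Dusp2 call did not hold without plate 2, 3 or 5 (edgeR adjusted p 0.167, 0.147 and 0.0664, log2 fold changes -0.65, -0.75 and -0.88).

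Other lists did not pass camera. Of the myeloid progenitor list, 2 of 4 fell and 1 rose (adjusted p = 0.0854), with the granule protease Prtn3 at -0.56 ± 0.12 and the chaperone Calr at 0.39 ± 0.10. The erythroid list (adjusted p = 0.0936) had 1 of 6 down, the transcription factor gene Gfi1b (-1.06 ± 0.26; edgeR adjusted p = 0.132 and log2 fold change -0.76 without plate 2). That list passed without plate 4 (camera adjusted p = 0.000194), with cells of at least 1000 UMIs (median -1.44 against -0.46, 4 of 6 down, 3.0e-06) and with CFP corrected for scatter width and side scatter (-0.73, 2.1e-07, chosen after seeing the data). With the 10 haemoglobin-rich cells left out it passed too (-0.28, 0.0175), and among the 50% of cells lowest in S and G2/M UMIs it passed upwards (0.25, 0.00037, 2 of 6 up), both settings chosen after seeing the data. Its median was 0.35 without plate 5. These 10 cells held 1407 UMIs of the list's Hba-a2. The multipotent progenitor list (adjusted p = 0.0750) had 1 of 7 down, Cd27 (-0.75 ± 0.20). Cd27 did not pass without plate 3, 4 or 5 (edgeR adjusted p 0.0553, 0.0936 and 0.124, log2 fold changes -0.74, -0.60 and -0.65). Cd34 was at 0.43 ± 0.26. The multipotent progenitor list passed with cells of at least 1000 UMIs (-0.52, 3 of 7 down, camera adjusted p = 0.0183). In settings chosen after seeing the data, it passed with fractions matched on UMIs per cell (-0.55, 0.0247) and CFP corrected for scatter width and side scatter (-0.42, 0.00797). The megakaryocyte list had 0 of 8 called by edgeR (3 at an unadjusted p under 0.05, 0 by DESeq2; camera adjusted p = 0.191), with Vwf at 0.78 ± 0.40.

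The retinoic acid response list, the signal that drives the reporter, had 0 of 7 tested genes called by edgeR, 0 at an unadjusted p under 0.05 and 0 by DESeq2 (median -0.17, camera adjusted p = 0.588), with Meis1 at -0.26 ± 0.21. The interferon list had 2 of 14 down (adjusted p = 0.0638; 0.0237 without plate 4, 0.0223 with cells of at least 1000 UMIs and 0.0400 with CFP corrected for forward scatter), Rtp4 (-1.21 ± 0.31; edgeR adjusted p = 0.0695 and log2 fold change -1.05 without plate 4) and Ly6e (-0.29 ± 0.09; not called without plate 2, 4 or 5, with log2 fold changes of -0.20, -0.26 and -0.35). Of the nucleolus and translation list, 4 of 30 rose and 2 fell (adjusted p = 0.0638; 0.0277 with the cells highest in S and G2/M UMIs left out and 0.0410 with fractions matched on UMIs per cell), with Nme1 at 0.71 ± 0.16 (edgeR adjusted p = 0.0816 and log2 fold change 0.53 without plate 5) and the elongation factor gene Eef1a1 at -0.35 ± 0.06. Among all alternatives run, the interferon list stayed without a camera call in 9 of 15 and the nucleolus and translation list in 12 of 15. Glycolysis had 1 of 11 up and 2 down (adjusted p = 0.932), with Ldha at 0.55 ± 0.13 (edgeR adjusted p = 0.0520, 0.47 without plate 3) and Aldoa at -0.56 ± 0.13 (0.0732, -0.40 without plate 4). MHC class I had 0 of 10 called by edgeR (1 at an unadjusted p under 0.05, 0 by DESeq2; camera adjusted p = 0.932). The single tested genes of the lymphoid progenitor, mast cell, mature neutrophil and endothelial lists were not called. By fry, which tests the genes of a list without the other genes, every list with a camera call passed. The myeloid progenitor (fry adjusted p = 0.0066), interferon (0.0111), nucleolus and translation (0.0134) and multipotent progenitor (0.0145) lists passed fry too. The megakaryocyte (0.0757), retinoic acid (0.130), erythroid (0.543), glycolysis (0.912) and MHC class I (0.912) lists did not.

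**Figure D2:**
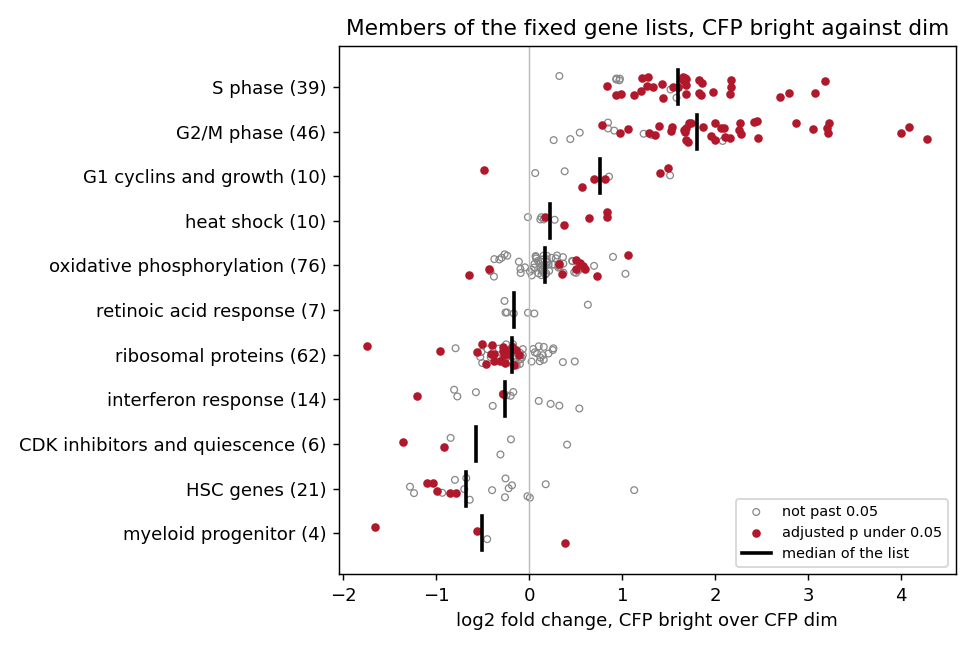
The log2 fold change of CFP bright over CFP dim for each tested member of 11 fixed lists, with the number tested in brackets. Red points passed an adjusted p of 0.05 in edgeR, open points did not, and black bars are list medians; the S phase (1.60) and G2/M (1.80) lists lie far to the right and the HSC genes (-0.68) to the left.

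Over all genes, 430 of 4658 passed between bright and dim cells, 260 higher and 170 lower in bright cells (987 at an unadjusted p under 0.05). Of these, 362 lie outside the S phase and G2/M lists. The called genes adjusted over the list alone numbered 37 for S phase, 40 for G2/M, 8 for growth (7 up), 6 for HSC genes, 28 for ribosomal proteins (27 down), 15 for oxidative phosphorylation (13 up), 5 for heat shock, 2 for quiescence and 0 for retinoic acid. By number of genes, the difference lay mostly between the bright fraction and the rest. Bright against intermediate cells gave 410 genes (269 of them shared with bright against dim), while intermediate against dim gave 1, Tuba1b (0.50), with 340 at an unadjusted p under 0.05. As a list, S phase genes were also higher in intermediate than in dim cells (median 0.62, camera adjusted p = 6.5e-18; adjusted p = 0.0741 with an estimated correlation), as were growth genes (0.31, 0.0157; adjusted p = 0.109 with an estimated correlation). Higher too were heat shock (0.17, 0.0157; adjusted p = 0.209 with an estimated correlation) and oxidative phosphorylation (0.080, 0.0231; adjusted p = 0.0943 with an estimated correlation). G2/M (0.17, 0.0783) and HSC genes (-0.20, 0.166) did not pass. The intermediate value lay between the other fractions for 394 of the 430 genes, and for 2005 of the 4228 genes that did not pass.

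Leaving out a plate gave 372 (plate 2), 287 (plate 3), 270 (plate 4) or 252 genes (plate 5). The fit without the plate block gave 115, and DESeq2 gave 173. When the 20% of cells with the most S and G2/M UMIs were left out of all fractions, 7 genes passed, among them Tuba1b (0.68), Lig1 (1.47) and the replication helicase gene Mcm6 (0.88, named after its value was seen). Leaving out a random 20% gave 342. That draw was not matched on CFP, and its fit tested 3963 genes, against 2804 with the cycling cells left out. The 2 counts therefore do not show how much of the drop is due to cycling cells.

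Genes outside the cell-cycle lists separated cells high and low in S and G2/M transcripts. The high set (205 cells) had an S and G2/M share of 3.19 ± 0.251% and the low set (512 cells) 0.627 ± 0.0646% by construction. The high set also had more UMIs per cell, with a median of 2193 ± 155 against 1353 ± 95.2, a ratio of 1.62. The linker histone gene Hist1h1b (3.77 ± 0.14), Spc24 (3.48 ± 0.23) and the centromere gene Cenph (3.36 ± 0.31), which were not on the lists, rose in the high set. Of the HSC list, 11 of 19 tested genes fell and 1 rose (median -0.89, camera adjusted p = 3.3e-11; adjusted p = 0.121 with an estimated correlation). Sult1a1 fell by 1.92 ± 0.44, the endothelial protein C receptor gene Procr by 1.69 ± 0.36, Mecom by 1.51 ± 0.30, Mllt3 by 1.48 ± 0.23, Ifitm1 by 1.46 ± 0.09, Pdzk1ip1 by 1.29 ± 0.13 and Hlf by 1.23 ± 0.16. Kit fell by 0.51 ± 0.17, a call that did not hold without plate 4 or 5 (edgeR adjusted p 0.0514 and 0.331, log2 fold changes -0.50 and -0.32).

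The growth list again moved up, with 6 of 10 genes higher and 1 lower (median 0.89, camera adjusted p = 0.000175; adjusted p = 0.206 with an estimated correlation). Ranbp1 (1.06 ± 0.12), Ran (0.98 ± 0.11) and Cdk4 (0.89 ± 0.10) rose, while cyclin D2, Ccnd2, fell by 0.99 ± 0.12. Of 74 oxidative phosphorylation genes, 20 rose and 2 fell (median 0.25, camera adjusted p = 0.000299; adjusted p = 0.263 with an estimated correlation), including Uqcrq (0.74 ± 0.15) and Atp5g3 (0.59 ± 0.10). The heat shock list had 4 of 10 up (camera adjusted p = 0.0261; adjusted p = 0.313 with an estimated correlation; 0.127 by camera without plate 3 and 0.0744 without plate 5), with Hspd1 at 0.94 ± 0.20 and Hsp90aa1 at 0.74 ± 0.14 (edgeR adjusted p = 0.0591 and log2 fold change 0.52 without plate 3). Of 61 ribosomal protein genes, 28 fell and 2 rose (median -0.23, camera adjusted p = 1.7e-12; adjusted p = 0.121 with an estimated correlation), with Rps9 at -0.51 ± 0.04. With sets matched on UMIs per cell, chosen after seeing the data, that median was -0.0199 and the camera adjusted p 0.139, and heat shock (0.17, 0.1997), the multipotent progenitor list (-0.32, 0.0551) and the interferon list (-0.16, 0.125) did not pass.

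Lower in the high set were 5 of 7 multipotent progenitor genes (camera adjusted p = 0.00542; adjusted p = 0.224 with an estimated correlation), among them Mycn (-1.40 ± 0.25), while Cd34 was at 0.11 ± 0.22. Also lower were 3 of 4 mature B, T and NK cell genes (0.00542; adjusted p = 0.206 with an estimated correlation), with Cd74 at -1.93 ± 0.23 and H2-Aa at -1.15 ± 0.22. Of the interferon list, 4 of 13 fell (0.00453; adjusted p = 0.206 with an estimated correlation), with Irf9 at -1.24 ± 0.32. Of the immediate early list, 2 of 4 fell (0.0235; adjusted p = 0.206 with an estimated correlation; 0.0543 by camera without plate 5), with Ier3 at -1.39 ± 0.37 (edgeR adjusted p = 0.108 and log2 fold change -0.95 without plate 5).

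The haemoglobin genes Hba-a2 (-3.79 ± 0.16), Beta-s (-3.70 ± 0.15) and Hbb-b1 (-2.00 ± 0.17) were much lower in the high set. Hba-a2 and Beta-s were lower in 4 of 4 plates, Hbb-b1 in 3 of 4. The 10 cells numbered 1 in the record held 1407, 1386 and 689 UMIs of the 3 genes. Without those cells, left out after seeing the data, Hbb-b1 was at 0.11 and did not pass, while Beta-s still passed. Over all alternatives Beta-s kept its call in 15 of 15 and Hba-a2 in 14 of 15. The fold changes of these 2 genes without those cells are not given here. The erythroid list had 3 of 7 down and 2 up (camera adjusted p = 2.6e-13; adjusted p = 0.121 with an estimated correlation), which without those cells did not pass (camera adjusted p = 0.352), and Car1, at 0.99 ± 0.29, turned to -0.30 without plate 3.

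Other lists did not pass camera in this comparison. They were quiescence (1 of 5 up, 2 down; adjusted p = 0.0521, and 0.0411 without plate 2), retinoic acid response (1 of 7 down; 0.109), nucleolus and translation (7 of 30 up, 2 down; 0.237), glycolysis (1 of 10 up, 3 down; 0.219), MHC class I (2 of 10 up, 3 down; 0.693), megakaryocyte (1 of 9 down; 0.7004) and myeloid progenitor (1 of 3 up, 1 down; 0.141). Within them Txnip (-1.17 ± 0.11) and Btg1 (-1.40 ± 0.45) fell, the latter not without plate 2, 4 or 5 (edgeR adjusted p 0.0698, 0.121 and 0.105, log2 fold changes -1.44, -1.19 and -1.27). Cdkn2c, a CDK inhibitor, rose by 1.96 ± 0.60, but not without plate 4 or 5 (0.0720 and 0.108, log2 fold changes 1.87 and 1.61). Eef1a1 was at -0.51 ± 0.05, Aldoa at -0.85 ± 0.12, Nfe2 at -0.57 ± 0.12, Prtn3 at -0.98 ± 0.11 and Vwf, not called, at -0.79 ± 0.33. Of the lists with 1 tested gene, Csf1r of the mature neutrophil and monocyte list fell (-1.52 ± 0.55; edgeR adjusted p = 0.105 and log2 fold change -1.41 without plate 5), and those of the lymphoid progenitor, mast cell and endothelial lists were not called. For glycolysis the median (0.03) and mean (-0.33) differ in sign, as they do for the megakaryocyte list (-0.09 and 0.02). Fry gave other calls for some lists by cell-cycle rank. Quiescence (fry adjusted p = 0.0082), retinoic acid response (0.0171, 7 of 7 genes negative) and myeloid progenitor (0.0433) passed it downwards. Of the lists with a camera call, oxidative phosphorylation (0.0622), erythroid (0.0967) and heat shock (0.156) did not pass fry.

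In all, 735 of 4312 genes outside the S phase and G2/M lists passed, 398 higher and 337 lower in the high set (1224 at an unadjusted p under 0.05). Adjusted over the list alone, 14 HSC genes (13 down), 9 growth genes (8 up), 25 oxidative phosphorylation genes (23 up), 38 ribosomal genes (34 down) and 5 interferon genes were called. The fit without the plate block gave 246 genes, DESeq2 299 and sets matched on UMIs per cell 275.

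Of the 4150 genes outside the lists tested in both comparisons, 350 passed by CFP and 704 by cell-cycle rank, and 280 passed in both, 163 upwards and 117 downwards and 0 in opposite directions. Independent lists would share 16.85 and 12.96. The same cells enter both comparisons, which raises this overlap, so fold changes were also taken from different wells. Across 1921 genes, CFP fold changes in wells of odd plate columns correlated with those of even columns at r = 0.511, and with cell-cycle fold changes of the other columns at r = 0.648 (covariances 0.155 and 0.222; genes are not independent replicates). The Spearman rho was 0.472 and 0.551.

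**Figure D3:**
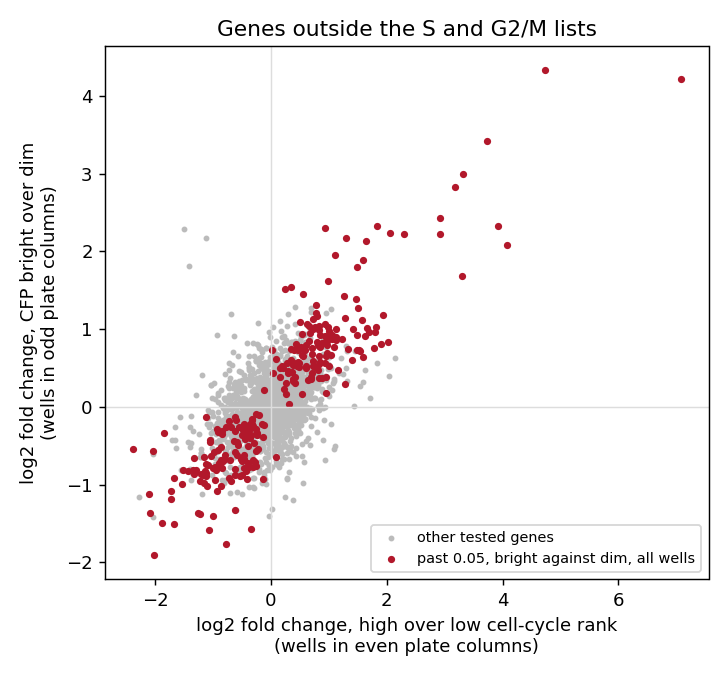
Each point is 1 of 1921 genes outside the S phase and G2/M lists, with the log2 fold change of high over low cell-cycle rank from wells in even plate columns (horizontal) against the log2 fold change of CFP bright over dim from wells in odd columns (vertical). Red points passed in the bright against dim comparison over all wells; the genes that rose and fell by CFP lie on the same side by cell-cycle rank, with few exceptions.

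CFP itself was higher in the cells of high cell-cycle rank. Of the high set, 66.6 ± 8.63% were CFP bright, against 10.0 ± 2.66% of the low set (SD, n = 4 plates) and 24.99% of all cells deep enough to be ranked; 2.83% and 22.3% were CFP dim. The difference in the bright share was 56.6 ± 11.1 percentage points with an exact sign-flip p of 0.125. The mean within-plate rank (0 to 1) of CFP differed by 0.362 ± 0.0605, the largest of the 12 channels. APC-Alexa Fluor 750 (0.316 ± 0.0244), forward scatter width (0.288 ± 0.0532), side scatter area (0.287 ± 0.0475) and DAPI (0.263 ± 0.0746) were also higher in the high set in 4 of 4 plates, as were PE-Cy7 (0.237), side scatter width (0.196), PE (0.192) and PE-Cy5 (0.0885). Alexa Fluor 700 was lower in 4 of 4 (-0.123 ± 0.0286). APC (0.0316, 2 of 4) and forward scatter area (0.00317, 3 of 4) went both ways. Each consistent channel had an exact p of 0.125 (adjusted over the 12 channels 0.15), and over 8 groups of wells, 2 from each plate and so not independent, the exact p for CFP was 0.0078 (adjusted 0.0104), the smallest that 8 groups allow.

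**Figure D4:**
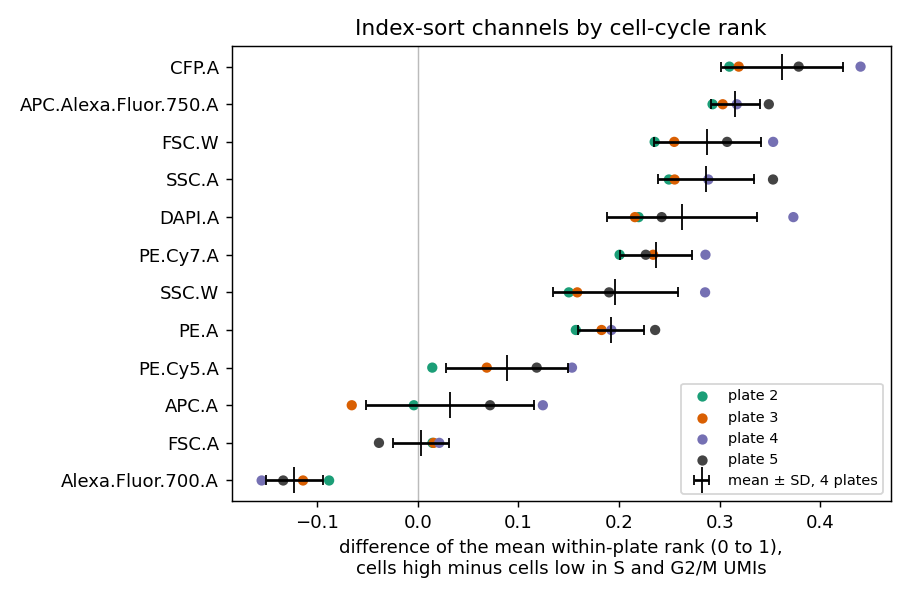
Difference in the mean within-plate rank (0 to 1) of each index-sort channel between cells high and low in S and G2/M UMIs. Coloured points are the 4 plates and black marks the mean and SD over plates; CFP has the largest difference (0.362), Alexa Fluor 700 is lower in every plate, and forward scatter area lies near 0.

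Transcripts of the sorting markers Kit and Ly6a, and of Cd34, which is not in the stated sorting gate, varied with some channels. The sorting-marker genes Slamf1 and Cd48 could not be tested. Of 32 tested gene and channel pairs, 8 passed 0.05 in edgeR with p adjusted over the pairs alone, 2 up and 6 down. Without the plate block 0 passed. With p adjusted over all genes of the channel, only Ly6a with APC-Alexa Fluor 750 (edgeR adjusted p = 0.0168) and with PE-Cy7 (0.0213) passed. No dye is linked to an antibody, so no pair had a direction set in advance and the pairs say nothing on whether wells and records were joined rightly. Ly6a was lower in cells high for APC-Alexa Fluor 750 (-1.91 ± 0.57) and for PE-Cy7 (-2.26 ± 0.67), and higher in cells high for Alexa Fluor 700 (1.76 ± 0.61). Cd34 was higher in cells high for PE-Cy7 (0.82 ± 0.30). It was lower in cells high for APC (-1.01 ± 0.27) and Vwf, the top gene of that channel, higher (2.95, edgeR adjusted p = 1.7e-05 over all genes). By number of genes called between the top and bottom 20% of cells, CFP came first (430), then APC-Alexa Fluor 750 (406) and forward scatter width (281), and forward scatter area gave 6.

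The leading variation among HSCs followed the cell cycle. In principal components computed without the S, G2/M and ribosomal genes, component 1 (0.808% of variance) correlated with the S and G2/M score across cells within plates (mean Spearman rho 0.673, percentile 100 among 1000 random lists). It correlated inversely with the HSC list score (rho -0.518, percentile 100), and its rho with the growth list score was 0.413 (percentile 100), while it was 0.428 with CFP and 0.406 with UMIs per cell. Component 2 (0.405%) followed the ribosomal score (rho 0.501, percentile 100). Cells are not replicates, so these are descriptions.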

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

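The tests with random draws of 50% of the cells, matching on UMIs, correction for scatter width and the 50% of cells lowest in S and G2/M UMIs were chosen after seeing the data, the random draws after the result that they test. Of 32 groups of 4 plate values, 2 had a plate far from the others, where chance gives about 5%. Forward scatter area differed by -0.0387 in mean rank between the cell-cycle sets in plate 5 and by 0.0145 to 0.0212 in the other plates. DAPI differed by 0.373 in plate 4 and by 0.216 to 0.242 in the others. In wells outside the comparisons, without an index record, the median was 224 UMIs; no background of empty wells was measured.

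The S and G2/M transcripts were higher in CFP-bright cells, which also had more UMIs. With fractions chosen within strata of UMIs per cell, 71.4% of the difference in share was left while the UMI ratio went from 1.75 to 1.04, which argues against sampling depth as the whole cause. With CFP corrected for scatter width and side scatter 83.2% was left, and 99.6% for forward scatter area, which is nearly unrelated to CFP (rho 0.104), so that its correction moves almost nothing and its bound, though met, decides nothing about size. Of the 35 splits of the 8 bright and dim libraries, 1, the real one, gave as many genes (430, the highest other 7), but those that keep the 2 libraries of every plate apart number 8 (highest other 3), too few for a share under 0.05. More cycling cells among bright HSCs stays as a hypothesis for this pool of cells.

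The HSC genes were lower in bright cells. Among the 50% of cells with the fewest S and G2/M UMIs, 21.3% of the list's median was left, as a larger share of cycling cells in the bright fraction would give. Over the 11 members tested there, the median was -0.14, against -0.70 in all cells and -0.53 to -0.15 in random draws of as many cells with the same CFP values, so it lay just beyond the edge of what fewer cells and a narrower CFP range gave. With fractions matched on UMIs per cell, 62.3% was left, between the bounds set, so a part played by UMIs per cell cannot be told apart.

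The ribosomal protein genes were lower in bright cells. Dilution by the added S and G2/M transcripts would give a smaller fall: with library size scaling the median lay 0.149 below the value that dilution gives (difference -0.149). With fractions matched on UMIs per cell, -6.75% of the median was left, which means that its sign turned, so the fall goes with UMIs per cell. The S and G2/M difference largely stayed in that setting (71.4%), so cycling alone did not carry the fall, and settings with fewer cycling cells, where the fall also went (median -0.0133 with cycling cells left out) or turned to a rise (0.067 in the lowest 50%, camera adjusted p = 0.0459), can narrow the UMI gap too (ratio 1.20 in the lowest 50%). Whether UMIs per cell stand for cell size, RNA content or capture was not tested.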

How the results depend on the processing

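Settings chosen after seeing the data were the 8 half-plates, the UMI strata, the correction for scatter width and side scatter, the 10 cells numbered 1 left out, and the lowest 50% or random parts of the cells. A 250-UMI minimum was not run, as every recorded well had at least 511 UMIs. The 430 genes by CFP became 261 (top against bottom 50%), 210 (UMI strata, 162 shared), 169 (random 50% of cells), 7 (cycling cells left out, 6 shared), 2 (lowest 50%, 0 shared), 173 with DESeq2 (128 up, 45 down; 173 shared) and 252 to 372 with a plate left out (252 without plate 5, 270 without plate 4). Without the plate block 115 passed (115 shared) and the 735 by cell-cycle rank became 246. Other settings gave 295 to 426 or 430. Against 260 up and 170 down, no count filter gave 324 and 53 and a minimum count of 3 gave 315 and 90. The 735 became 275 (UMI strata), 299 (DESeq2) and 499 to 632 with a plate left out, and 551 to 809 in other settings. No gene called in both a setting and the reported test changed direction. Against 10 lists by CFP, 5 passed with cycling cells left out (S phase, growth, heat shock and quiescence of the 10, and nucleolus and translation) and 7 to 11 with a plate left out. In the lowest 50% 2 passed, both upwards, against the sign of the reported median: erythroid (camera adjusted p = 0.00037) and ribosomal (0.0459). Leaving out cycling cells and keeping the lowest 50% chose cells by S and G2/M UMIs, which lowered the signal of those lists by that choice. The difference in share was 1.49 over 8 half-plates, not independent (exact p = 0.0078), 1.37 to 1.60 with a plate left out and positive in every plate in the other settings, from 0.560 for S phase alone to 1.97 for the top against bottom 10%. The 8 marker pairs became 5 at 1000 UMIs and 0 by edgeR without the plate block. Smaller sets test fewer genes; for the other changes the cause was not tested.

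List results by CFP for other widths of the fractions, filters and scalings are not given here, apart from the ribosomal list with library size scaling. List tests were not run with DESeq2. In the list settings given, the HSC list kept its call except with cycling cells left out (-0.15, camera adjusted p = 0.117) and the lowest 50% (-0.14, 0.419). S phase lost its call in the lowest 50% (0.38, 0.171), and G2/M there (0.26, 0.176) and with cycling cells left out (0.11, 0.260). Those settings chose cells by the UMIs of these same lists, so the signal of the lists was lowered by that choice. No conclusion is drawn from these lost calls. Of 278 list results by CFP, 202 kept direction and side of the threshold, 29 lost and 18 gained a call and 29 changed sign. By cell-cycle rank these were 208, 14, 3 and 11 of 236. Of 36 channel results they were 25, 0, 10 and 1, of 1079 results for named genes by CFP 869, 194, 3 and 13, and of 575 by cell-cycle rank 519, 52, 0 and 4. The component 1 correlation was 0.714 with unthinned counts. Depth limits what could be tested by CFP: 5 of 22 immediate early, 6 of 19 quiescence, 7 of 26 retinoic acid and 21 of 29 HSC genes.

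Medians that changed sign by CFP, cause not tested, were as follows. Glycolysis (-0.011): no plate block 0.051, forward scatter 0.0138, cycling cells left out 0.14, half-plates 0.11, lowest 50% 0.12, the 10 cells left out 0.079, scatter width 0.097, random 20% left out 0.13, random 50% 0.22, and -0.034 to 0.14 with a plate left out (positive without plate 3, 4 or 5). MHC class I (0.0013): 1000 UMIs -0.078, half-plates -0.0147, UMI strata -0.056, random 20% left out -0.0427, random 50% -0.0431, and -0.14 to 0.056 with a plate left out (negative without plate 2 or 5). Retinoic acid (-0.17): scatter width 0.0129, random 50% 0.0130, and -0.25 to 0.081 with a plate left out (positive without plate 2). Multipotent progenitor: cycling cells left out 0.14, lowest 50% 0.22. Erythroid: lowest 50% 0.25, and -1.12 to 0.35 with a plate left out (positive without plate 5). Ribosomal: UMI strata 0.0123, lowest 50% 0.067. Megakaryocyte: random 50% -0.20. By cell-cycle rank, glycolysis (0.025) gave -0.11 for the top 10%, -0.045 for 500 UMIs, -0.060 for UMI strata, -0.0225 without a filter, and -0.0273 to 0.0075 with a plate left out (positive without plate 3). Megakaryocyte gave 0.18 for the top 10% and -0.26 to 0.0205 with a plate left out (positive without plate 3). MHC class I gave -0.19 to 0.0180 (positive without plate 3 or 5). Forward scatter area gave -0.0129 without 8 abundant genes.

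Named genes that changed sign, none passing there, the cause not tested, were by CFP with cycling cells left out Top2a (-0.32, a G2/M list gene, so its signal was lowered by that choice), Hist1h1b (-0.54), Procr (0.46) and Eef1a1 (0.0173). In the lowest 50% they were Hist1h1b (-1.08), Ranbp1 (-0.055), Pdzk1ip1 (0.0096), Mllt3 (0.037), Txnip (0.0142) and Cd74 (0.14). Others were Cdkn1c (scatter width -0.052; -0.071 to 0.66 with a plate left out, negative without plate 5) and Calr (UMI strata -0.0417). By cell-cycle rank they were Cd34 (-0.0172 to 0.22 with a plate left out, negative without plate 3), Hbb-b1 (the 10 cells left out 0.11, by that choice) and Car1 (top 10% -0.51; -0.30 to 1.73 with a plate left out, negative without plate 3).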

Other observations

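The test of fewer cells in the fit was chosen after its result was seen. The whole numbers 1 to 10 in the record, whose meaning is not stated, went with transcripts, and the genes named here were chosen after their values were seen. Number 1 (10 cells) held haemoglobin, with 19.3% of its UMIs from the erythroid list. Number 2 (117 cells) had more Sult1a1, Mllt3 and Procr, and number 3 (169 cells) more Ifitm1 and Cd74. Number 9 (188 cells) had a median of 2340.5 UMIs, 2.75% of its UMIs from the S and G2/M lists and 60.0 ± 9.89% bright cells. Number 10 (42 cells) had 3.64% of its UMIs from these lists and 58.7 ± 29.4% bright cells, and number 4 (330 cells) 7.03% bright cells (SD, n = 4 plates). These list percents are of unthinned UMIs summed over the cells of a plate, so they are not the share of thinned UMIs given above. Among histone genes, whose UMIs can be shared, 12 of 15 tested rose with CFP and 0 fell (median 2.51), a group chosen after seeing the data.

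A hypothesis is that CFP differences outside the S phase and G2/M lists follow cell-cycle status. The correlation of CFP fold changes with cell-cycle fold changes from other wells was 127% of that between CFP fold changes from different wells, which met the bound set. Cell-cycle fold changes from different wells correlated more closely (0.742) than CFP fold changes did (0.511), which can raise that percentage. Genes outside the lists also include histone and mitotic genes such as Hist1h1b and Spc24, whose large fold changes can raise it too. By Spearman, rho was 0.551 for CFP with cell-cycle fold changes and 0.472 between CFP fold changes. Both comparisons also differed in UMIs per cell (ratios 1.62 and 1.75), and no version matched on UMIs was run. The test therefore cannot tell cell-cycle status from UMIs per cell. Among the 50% of cells lowest in S and G2/M UMIs, edgeR called 2 genes by CFP, Hba-a2 (2.64) and Beta-s (1.78), named after their values were seen. Both are haemoglobin genes, were at -0.48 and -0.47 over all cells without passing, and have 1407 and 1386 UMIs in the 10 cells numbered 1; whether the calls hold without those cells was not tested. Random draws of as many cells with the same CFP values called 11 to 45 genes, and 0 of 20 called as few. Outside the S and G2/M lists, whose UMIs chose the cells, the draws called 4 to 31, against 2. Fewer cells in the fit were therefore not the whole cause. Over all cells 362 genes were called outside the lists. The draws lay far below that, so fewer cells and a narrower CFP range also lowered the count. The draws were not matched on UMIs per cell (median 1172 to 1251, against 1162.5) and tested 1698 to 2009 genes, against 1500, so a part played by depth stays open. The reverse order, in which what raises CFP drives cells into cycle, was not tested, and CFP protein may also build up in larger or dividing cells.

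For genes that vary with cell-cycle rank, of the 32 splits of the 8 libraries that could be fitted, 1, the real one, gave as many genes (735, the highest other 1). Of these, 8 splits keep the 2 libraries of every plate apart (735, the highest other 0), too few for a share under 0.05. Ranking cells by any list of expressed genes was tested with 50 random lists matched on expression: 0 gave as many (highest 84, median 8).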
